A study of Mus musculus with 10 samples.

How the data were processed

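RNA was sequenced from eosinophils purified by flow cytometric sorting from the lungs of male mice, 5 libraries from P2ry14-null animals and 5 from wild-type C57BL/6J animals (WT). Per the labels' protocols, RNA was extracted with TRIzol Plus, treated with DNase, cleaned on PureLink columns and made into libraries with an Illumina TruSeq RNA kit. The authors deposited whole-number read counts per gene for all 10 libraries in a single table, which was the only processed table used here. Per the submitters' processing notes, the tools were STAR 2.5, Subread with featureCounts 1.5.0-p1, and DESeq2, on the mouse genome build mm10. The annotation release, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. Without a known strand setting, reads of a gene and of a gene on the opposite strand cannot be told apart. Because the treatment of reads that match several places is unknown, close gene copies are uncertain as single genes. Examples are Hspa1a and Hspa1b, Hba-a1 and Hba-a2, the Ear genes and the ribosomal protein genes with their pseudogenes.

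The table listed 35725 gene rows with a symbol, a gene identifier and mm10 coordinates, of which 30 repeated a symbol and were kept as separate rows. It listed 0 genes of the mitochondrial chromosome, so no mitochondrial share was computed. By identifier, 34762 rows (97.3%) matched the RefSeq annotation of GRCm38.p6, the assembly behind mm10, and 34637 of these (99.6%) overlapped the RefSeq position. Exons and overlaps were read from GENCODE vM21 on GRCm38. Column names equalled the sample titles, and each group and replicate number came from those titles. Chi-square tests over genes gave 24.2 or more per gene for every pair of libraries within a group, so no pair agreed within sampling noise and each library was counted once. The labels do not say that each library came from a separate mouse, and p-values then measure only the spread between these samples, which may be technical.

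Total counts ran from 67.2 to 185 M reads (M, 1e+06) per library. A count of 3 reads, the upper limit that a count of 0 allows, equals 0.0447 counts per 1e+06 reads (CPM) in the shallowest library and 0.0162 in the deepest. Such limits cover counting error only. edgeR 4.0.16 in R 4.3.3 was run on the deposited counts with TMM factors, the default low-count filter and a model of genotype alone, and the quasi-likelihood F test was adjusted by Benjamini-Hochberg over the 15586 genes kept, with a threshold of 0.05. CPM values use the TMM-scaled library sizes, errors of log2 fold changes are the fold change divided by the square root of F, and fold changes are P2ry14-null minus WT. The common biological coefficient of variation was 12.3% and the median SE of a log2 fold change 0.0894. On counts simulated from these libraries for the same comparison over 15586 genes, the test recovered 24% of 50 genes changed 1.25-fold, 50% of 50 changed 1.5-fold, 82% of 50 changed 2-fold and 96% of 50 changed 4-fold. Of its 137 calls on these counts, 7 (5.11%) were false. The real comparison gave 6 calls. With fewer calls the adjusted threshold asks for a smaller p, so the recovered shares may be too high for the real data. In the same simulation, a list of 20 genes moved 1.2-fold gave a camera p of 2.27e-13 and a list that was not moved gave 0.243. Simulated genes were drawn independently, so this does not test lists whose members correlate, such as the NF-kB list (estimated correlation 0.361).

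Single values were compared by a two-sided exact permutation test over all assignments of 5 against 5 libraries, whose smallest p is 0.0079. Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 27 lists. The lists covered eosinophil, nucleotide receptor, type 2, chemotaxis, Gi and actin, inflammatory, interferon, activation, survival, lipid mediator, cell cycle, metabolic, ribosomal and stress genes, antigen presentation, markers of 9 other cell classes, and the chromosome neighbours of P2ry14. P2ry14 itself was in none of the lists. Calls within 10 Mb of P2ry14 were compared with the rest of the genome by Fisher's exact test. Principal components were taken over the 500 most variable genes, and 3 components were tested.

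Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took P2ry14, then up to 12 genes per direction past the threshold with the largest fold change, a mean of at least 5 CPM in the higher group and a symbol other than a provisional or pseudogene name. Where fewer than 8 per direction met it, genes with the smallest p filled up to 8, as values that did not pass. In each list it took up to 4 members past the threshold, or else up to 2 with the smallest p; a gene that this rule took is not reported here. Other genes named were chosen after their values were seen: Mgst2, Gm30351, Med12l, P2ry13 and F630111L10Rik near P2ry14, further NF-kB genes (Nfkbia, Tnf, Nfkbiz, Tnfaip3 and Ccl3), the levels of eosinophil, nucleotide and adenosine receptor, ectonucleotidase and UDP-glucose genes, the heat shock genes, and the genes of single or paired libraries, Tmem181b-ps included.

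Alternatives were DESeq2 1.42.0, limma-voom with and without quality weights, DESeq2 size factors or upper-quartile factors in edgeR, a robust dispersion, no filter beyond 1 read, a filter of 5 CPM in 5 libraries, the replicate number as a block in edgeR and in DESeq2, the mean of the other-cell markers as a covariate, a fold of at least 1.2, each library left out, an estimated correlation and fry for the lists, all tested genes for the components, and windows of 5 and 20 Mb. Another 2, each leaving out a pair of libraries, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads, splice junctions and genotypes of the libraries were not analysed here.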

Results

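P2ry14 encodes a Gi-coupled receptor for UDP-glucose and related UDP-sugars. The comparison asked how the transcripts of lung eosinophils differ between mice without this receptor and wild-type mice in a model of allergic asthma. Eosinophils are granulocytes that gather in allergic airways. Mice were sensitized through the oropharynx with 50 µg of ovalbumin and 20 µg of Aspergillus oryzae protease on a pair of occasions, given a 1% ovalbumin aerosol 7 days after the last of them, and eosinophils were sorted 16 h after that challenge. Total counts of WT libraries 1 to 5 were 133, 118, 185, 161 and 130 M reads (M, 1e+06). Those of P2ry14-null libraries 1 to 5 were 67.2, 149, 150, 129 and 151 M.

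By CPM, which is not scaled for gene length, P2ry14 stood at rank 966 of 15586 tested genes in WT eosinophils. WT libraries 1 to 5 held 226, 206, 229, 190 and 206 CPM of P2ry14. P2ry14-null libraries 1 to 5 held 24.2, 23.4, 21.8, 24.1 and 22.5 CPM. The mean fell from 211 ± 16.0 to 23.2 ± 1.02 CPM (SD, n = 5 each), which leaves 11.0% of the WT level. The log2 fold change was -3.19 ± 0.06 (SE; edgeR adjusted p = 3.74e-12), and the exact permutation p was 0.0079, the smallest that this design allows. P2ry14 (gene ID 140795) lies on chromosome 3 at 59114623 to 59153492 of mm10, on the minus strand, within the span of Med12l on the plus strand. In the annotation, P2ry14 and Med12l share 0 exon bases. Counts per gene do not show which exons gave the remaining reads, and an uncharacterised transcript on the same strand, F630111L10Rik, overlaps its 5 prime end.

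Beyond the target, few transcripts differed. Gpr171, a G protein-coupled receptor gene next to P2ry14, rose from 1.60 ± 0.32 to 23.9 ± 1.86 CPM (SD, n = 5 each). P2ry12, the ADP receptor gene of platelets and microglia, rose from 1.59 ± 0.30 to 2.93 ± 0.22 CPM. Il18rap, the accessory chain of the interleukin-18 receptor, fell from 87.7 ± 3.15 to 71.6 ± 1.30 CPM. Mgst2, a microsomal glutathione S-transferase, fell from 0.740 ± 0.099 to 0.190 ± 0.053 CPM, and Gm30351, a gene without a known function, fell from 0.124 ± 0.041 to 0.0083 ± 0.0076 CPM. The edgeR test called 6 of 15586 genes, 2 higher and 4 lower in P2ry14-null, P2ry14 included. Log2 fold changes were 3.90 ± 0.12 for Gpr171 (SE; edgeR adjusted p = 7.31e-10), 0.88 ± 0.13 for P2ry12 (edgeR adjusted p = 0.028) and -0.29 ± 0.04 for Il18rap (edgeR adjusted p = 0.018). They were -1.94 ± 0.19 for Mgst2 (edgeR adjusted p = 7.50e-04) and -3.65 ± 0.49 for Gm30351 (edgeR adjusted p = 0.018). Each of the 6 genes separated all 5 P2ry14-null from all 5 WT libraries. The 6 were called on these same values, so their separation is no further support. Of all 15586 tested genes, 101 (0.648%) separated the groups, where chance gives 0.794%. At an unadjusted p under 0.05 there were 644 genes, 228 higher and 416 lower, where 779.3 are expected by chance. DESeq2 called 18 genes, 7 higher and 11 lower, and kept 5 of the 6, with no adjusted p for Gm30351. With single libraries left out the count lay between 3 and 5, and Il18rap, P2ry12 and Gm30351 then missed the threshold in 7, 9 and 8 of the 10 such fits. Il18rap passed without WT library 1, 3 or 5, P2ry12 without WT library 3, and Gm30351 without WT library 1 or 2.

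**Figure D1:**
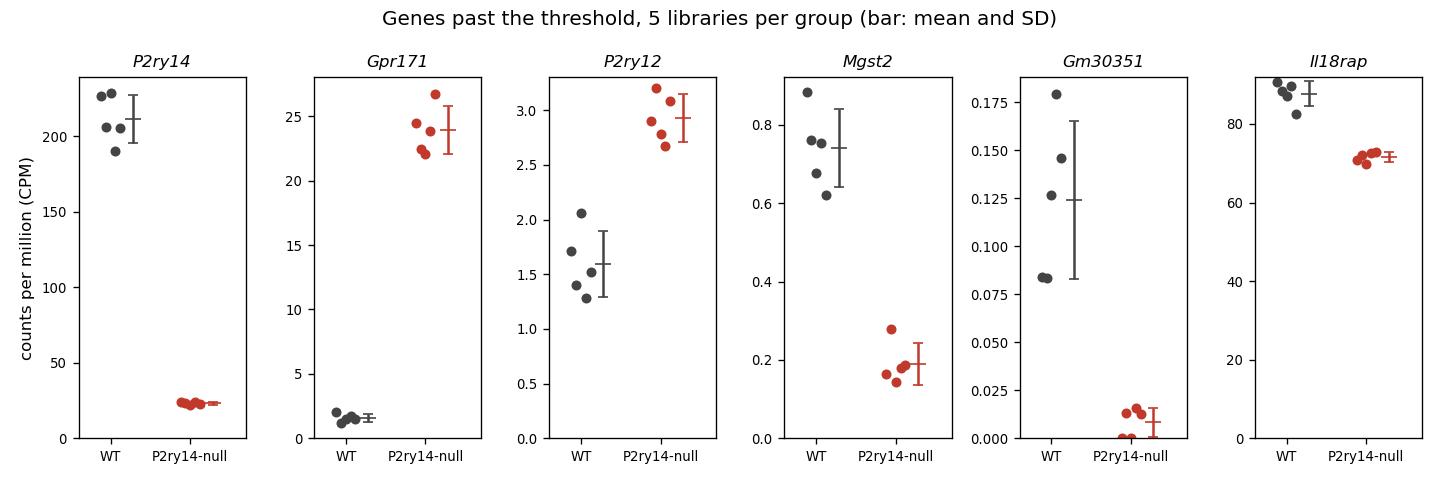
CPM (vertical axes, linear and starting at 0) of the 6 called genes in 5 WT (grey) and 5 P2ry14-null (red) libraries; bars show the mean and SD. The groups do not overlap for any of the 6 genes, which were called on these same values. The P2ry14-null libraries hold 21.8 to 24.2 CPM of P2ry14.

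Of the 5 called genes other than P2ry14, 4 lie near it on chromosome 3. Gpr171 (gene ID 229323), at 59096448 to 59101821 on the minus strand, is the next gene downstream of P2ry14 on that strand, with a gap of 12.8 kb. P2ry12 (gene ID 70839), at 59216271 to 59262831 on the minus strand, lies 62.8 kb upstream. In the annotation Gpr171 shares 0 exon bases with Med12l and P2ry12 shares 9. Mgst2 (gene ID 211666; 51660360 to 51682675, plus strand) and Gm30351 (gene ID 102632211; 52933249 to 52956278, plus strand) lie 7.43 and 6.16 Mb away. Other neighbours did not pass: P2ry13, between P2ry14 and P2ry12, had 5.65 CPM in WT and 6.01 in P2ry14-null, and Med12l, which spans this cluster, had 5.61 and 6.60. Within 10 Mb, 4 of 72 tested genes were called, P2ry14 not counted, against 1 of 15513 elsewhere (Fisher's exact test, two-sided, p = 2.09e-09). From 0.5 to 10 Mb, 2 of 66 genes were called (Fisher's exact p = 5.29e-05). Mgst2 rested on 81 to 123 reads per WT library and 11 to 43 per P2ry14-null library. Gm30351 rested on 91 reads over all WT and 6 over all P2ry14-null libraries, a rate ratio of 7.43% (95% exact interval 2.66% to 16.8%, counting error only). Il18rap (gene ID 16174) lies on chromosome 1 at 40515362 to 40551707 on the plus strand.

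**Figure D2:**
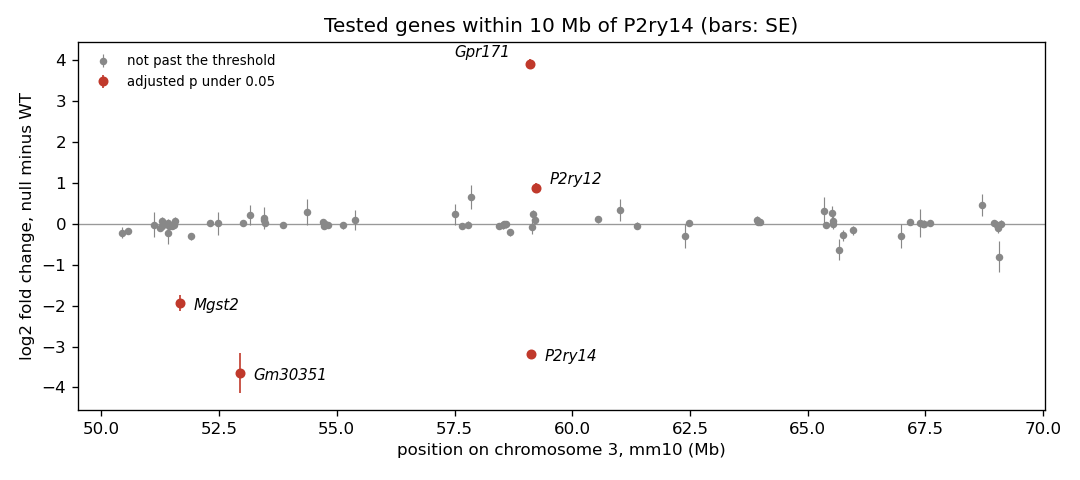
Log2 fold change of P2ry14-null over WT (vertical axis; bars, SE) by gene position on chromosome 3 of mm10 in Mb, for tested genes within 10 Mb of P2ry14. Red points are past an adjusted p of 0.05: Gpr171 at 3.90, P2ry12 at 0.88, P2ry14 at -3.19, Mgst2 at -1.94 and Gm30351 at -3.65.

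With all 10 libraries and no replicate block, no further gene passed the threshold in edgeR. Without P2ry14-null library 4, edgeR also called the pseudogene Tmem181b-ps. Among those with the smallest p were several genes lower in P2ry14-null, given as values. Log2 fold changes were -0.71 ± 0.16 for the cytokine Il6 (43.4 against 71.0 CPM), -0.65 ± 0.14 for Hdc, the histamine-forming enzyme, and -0.74 ± 0.15 for Soat2, an enzyme of cholesterol esterification. They were -0.47 ± 0.09 for the heat shock co-chaperone Dnajb1, -0.29 ± 0.06 for interferon-inducible Ifi27, -0.23 ± 0.04 for Tmem86b and -0.29 ± 0.07 for the transcriptional co-regulator Cited2. Their edgeR adjusted p ran from 0.354 to 0.770. DESeq2 called Il6, Hdc, Soat2, Dnajb1, Ifi27, Tmem86b and, on the higher side, Dynlt1b. With the replicate number as a block, edgeR called Il6, Hdc and Soat2, and DESeq2 called these 3, Dnajb1, Ifi27, Cited2, Dynlt1b and Retnla. Same-numbered libraries did not deviate together (correlations from -0.093 to 0.094), so calls with this block, here and below, are given as an alternative only. Also higher stood Retnla, a secreted protein of type 2 inflammation, at 0.43 ± 0.12 (2383 against 1772 CPM), and Dynlt1b at 0.67 ± 0.17. Cfap99, Stag3, Arsg, Tmem181a and Mlst8 lay between 0.15 and 0.37, and edgeR adjusted p of these 7 genes ran from 0.770 to 0.999.

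Genes of the eosinophil program did not differ past the threshold. Siglecf, a surface lectin of mouse eosinophils, had 1282 CPM in WT and 1232 in P2ry14-null, the eotaxin receptor Ccr3 1369 and 1428, and the granule protein Prg2 813 and 859. Of 18 eosinophil identity and granule genes, 0 passed over all genes and 1, Prg3, passed adjusted over the list alone (log2 -0.43 ± 0.11), while Epx was at 0.23 ± 0.07. Over all genes Prg3, and Retnla of the type 2 list below, passed in DESeq2 with the replicate block. The eosinophil identity list had a median log2 fold change of -0.05 (camera adjusted p = 0.132). In the list of 19 nucleotide receptor and UDP-glucose metabolism genes, P2ry12 was the sole gene called over all genes and also the sole gene adjusted over the list alone (median 0.01, camera adjusted p = 0.885). Of 20 type 2 cytokine and receptor genes, 0 passed over all genes and 2 adjusted over the list alone, Retnla and Il2rg (log2 -0.21 ± 0.06). Their median was -0.05, as camera's direction, and their mean 0.16 (camera adjusted p = 0.266). No gene passed over all genes or adjusted over the list alone in these lists: 23 chemotaxis and adhesion genes (median -0.01, mean 0.003, camera adjusted p = 0.541; Icam1 -0.26), 26 Gi signalling and actin genes (-0.04, 0.144; Pfn1 -0.11, Rock2 0.11), 20 apoptosis and survival genes (-0.04, 0.157; Birc3 -0.18, Mcl1 -0.16), 15 lipid mediator genes (0.01, 0.695; Alox5ap -0.13, Ptges3 -0.26), 19 cell cycle genes (-0.03, 0.695; Pcna -0.15, Ccnb1 0.55) and 22 glycolysis and hypoxia genes (-0.06, 0.0569; Slc2a1 -0.16, Ldha -0.12). Medians and means differ in sign in the chemotaxis, lipid mediator and cell cycle lists.

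Inflammatory and stress genes lay lower in P2ry14-null as sets under the preset correlation, by small amounts. Of 21 NF-kB response genes, 20 had a log2 fold change below 0, with a median of -0.20. None of the 21 passed over all genes, and 6 passed adjusted over the list alone: Il6, Relb (-0.27 ± 0.07), Nfkbia, Tnf, Nfkbiz and Tnfaip3. Over all genes Il6 passed in DESeq2 and in edgeR with the replicate block, and Il6, Nfkbia, Nfkbiz and Ccl3 passed in DESeq2 with that block. The list passed camera with the preset correlation (adjusted p = 2.32e-09) and did not with an estimated correlation (adjusted p = 0.421). Of 24 immediate early and dissociation stress genes, 20 lay below 0 (median -0.07). None passed over all genes and 5 passed adjusted over the list alone: the early growth gene Egr1 (-0.70 ± 0.18) and 4 heat shock genes, Dnajb1, Hsp90aa1, Hspa1b and Hspa1a. Over all genes Dnajb1 passed in DESeq2, and Dnajb1 and Hspa1a in DESeq2 with the replicate block, as did Cxcl10 of the interferon and Cd69 of the activation genes below. The immediate early list had a camera adjusted p of 1.22e-05, and the adjusted p = 0.421 with an estimated correlation. All 24 ribosomal protein genes lay below 0 (median -0.17; Rps14 -0.22, Rps18 -0.19), with 0 past the threshold over all genes and 16 adjusted over the list alone (camera adjusted p = 1.80e-18; adjusted p = 0.421 with an estimated correlation). Of 24 interferon response genes 21 lay below 0 (median -0.20; Gbp2 -1.01 ± 0.35, Cxcl10 -0.41 ± 0.15), with 0 passing either adjustment (camera adjusted p = 4.14e-05; adjusted p = 0.585 with an estimated correlation). Of 20 endoplasmic reticulum stress genes 15 lay below 0 (median -0.10; Hspa5 -0.34, Trib3 -0.23), with 0 passing either adjustment (camera adjusted p = 0.0021; adjusted p = 0.421 with an estimated correlation). Of 18 activation surface genes 14 lay below 0 (median -0.07), 0 passed over all genes and 1, Cd69, adjusted over the list alone (-0.47 ± 0.12; camera adjusted p = 0.0026; adjusted p = 0.427 with an estimated correlation). Of 22 nuclear oxidative phosphorylation genes 21 lay below 0 (median -0.05; Cycs -0.15, Atp5b -0.06), with 0 passing either adjustment (camera adjusted p = 0.016; adjusted p = 0.853 with an estimated correlation).

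With single libraries left out, the medians of some of these lists moved by over 1.5 times while camera with the preset correlation kept them past the threshold. Interferon genes had a median of -0.111 without WT library 1 (Gbp2 -0.66) and -0.131 without WT library 3, and over all alternatives it ran from -0.281 to -0.0761. Immediate early genes had -0.135 without WT library 3, -0.127 without P2ry14-null library 3 and -0.038 without P2ry14-null library 1. Over all alternatives their median ran from -0.135 to -0.024, and 1 of 22 fits with the preset correlation lost the call. Endoplasmic reticulum stress genes had -0.058 without WT library 4 and -0.053 without P2ry14-null library 5. Activation genes missed the threshold without WT library 1 (median -0.037, camera adjusted p = 0.051). Oxidative phosphorylation genes missed it without WT library 1, 2 or 4 or P2ry14-null library 3 or 5 (camera adjusted p from 0.052 to 0.939). Their median was -0.005 without WT library 1 and -0.083 without WT library 3. Log2 fold changes of some named genes also moved by over 1.5 times. Without WT library 1, Mcl1 was at -0.09, Slc2a1 -0.10, Ldha -0.06, Cycs -0.10 and Atp5b -0.04. Without WT library 3, Rock2 was at 0.17, Ptges3 -0.15 and Ccnb1 0.86. Without WT library 4, Pcna was at -0.08 and Hspa5 -0.21. Retnla was at 0.28 without P2ry14-null library 4, and Atp5b at -0.04 without P2ry14-null library 5.

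Heat shock genes moved together with the inflammatory genes from library to library. Mean log2 CPM of Hspa1a, Hspa1b, Dnajb1, Hsp90aa1 and Hspa8 was 4.32 in P2ry14-null and 5.20 in WT (n = 5 each), a difference given without a test because these 5 genes were chosen after their values were seen. The mean over the NF-kB genes differed with an exact permutation p of 0.032. After group means were removed, both scores correlated across the 10 libraries (Pearson's r = 0.680, permutation p = 0.0063; Spearman's rho = 0.770, permutation p = 0.012), as the 1 relation computed. Without P2ry14-null libraries 3 and 5, the 2 farthest from the median of the heat shock score with group means removed, r was 0.664. With the heat shock score as a covariate, the median of the NF-kB list was -0.0016 (camera adjusted p = 0.994) and P2ry14 and Gpr171 were the 2 genes called. The other 4 called genes missed the threshold there with wider SE, at log2 fold changes of -0.29 ± 0.07 for Il18rap, 0.74 ± 0.19 for P2ry12, -2.0 ± 0.33 for Mgst2 and -3.78 ± 0.84 for Gm30351 (edgeR adjusted p from 0.294 to 1.00).

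**Figure D3:**
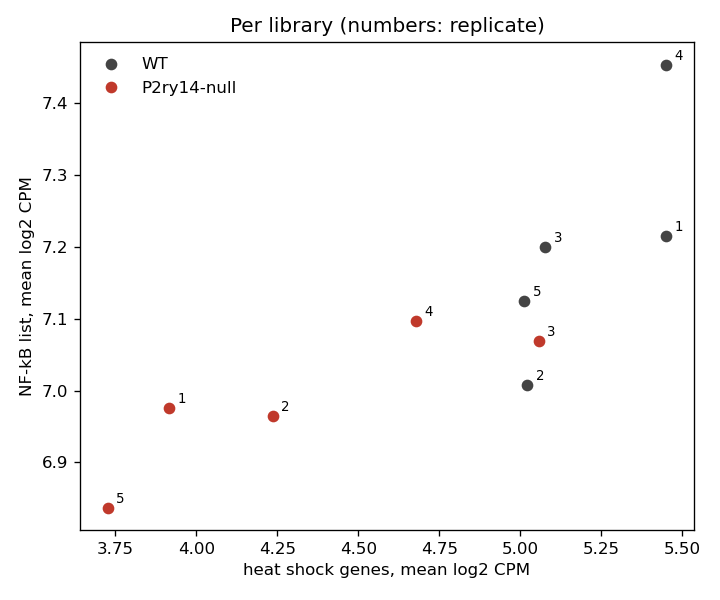
Mean log2 CPM of 5 heat shock genes (horizontal axis) and of 21 NF-kB response genes (vertical axis) in each of 5 WT (grey) and 5 P2ry14-null (red) libraries, numbered by replicate. Libraries with a higher heat shock score have a higher NF-kB score within the groups as well as between them (r = 0.680 with group means removed).

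In markers of other cell types 1 library stood apart. P2ry14-null library 2 had 63.6 CPM of the class II gene H2-Eb1 against 6.62 to 12.3 in the other 4 P2ry14-null libraries, and 19.9 CPM of the alveolar type II cell gene Sftpc. Without this library, the medians of the class II and alveolar macrophage lists turned from 0.35 to -0.35 and from 0.23 to -0.25. With it, neither list passed: 8 class II genes had a camera adjusted p of 0.695 (H2-Ab1 0.50, H2-Eb1 0.64) and 14 alveolar macrophage genes also 0.695 (Fabp4 0.63, Fabp5 0.65). Mast cell and basophil genes lay lower, 7 of 7 below 0 with a median of -0.59, with 0 passing over all genes and Hdc and Cpa3 (-0.67 ± 0.19) adjusted over the list alone (camera adjusted p = 2.43e-06; adjusted p = 0.215 with an estimated correlation). Over all genes Hdc passed in DESeq2, and in edgeR and DESeq2 with the replicate block. Neutrophil genes lay higher, 10 of 11 above 0 with a median of 0.16 and 0 passing either adjustment (Ly6g 0.41, S100a8 1.01; camera adjusted p = 0.016; adjusted p = 0.520 with an estimated correlation). Endothelial and fibroblast genes lay higher, 9 of 11 above 0 with a median of 0.24, 0 passing over all genes and 1, Eln, adjusted over the list alone (0.63 ± 0.17; Kdr 1.29; camera adjusted p = 0.016; adjusted p = 0.520 with an estimated correlation). Neutrophil genes missed the threshold without WT library 2 or 3 or P2ry14-null library 2 or 4 (camera adjusted p from 0.060 to 0.127), with a median of 0.032 without P2ry14-null library 4. Endothelial and fibroblast genes missed it without WT library 3 or 4 or P2ry14-null library 2 or 4 (camera adjusted p from 0.139 to 0.217). Their median was 0.051 without P2ry14-null library 2, 0.392 without WT library 1 and 0.398 without P2ry14-null library 5. Mast cell and basophil genes kept their call, with medians of -0.380 without WT library 1 and -0.365 without P2ry14-null library 1. Several single genes also rested on P2ry14-null library 2. Without it, log2 fold changes were 0.15 for Sftpb, 0.37 for Cldn18, 0.49 for Kdr, 0.38 for S100a8, 0.18 for Cd4 and 0.26 for Cd8b1, and below 0 for Pf4 (-0.30), Pax5 (-0.42), Mzb1 (-0.88), H2-Eb1 (-0.46), H2-Ab1 (-0.39), Fabp4 (-0.04) and Fabp5 (-0.15). No gene passed either adjustment among 16 monocyte and dendritic cell genes (median 0.33, camera adjusted p = 0.144; Ly6c2 -0.52, Clec9a 0.25), 17 T and NK cell genes (0.13, 0.277; Cd4 0.50, Cd8b1 0.41), 14 epithelial genes (0.40, 0.277; Sftpb 1.43, Cldn18 0.91), 10 B and plasma cell genes (0.04 with camera's direction down, 0.260; Pax5 0.19, Mzb1 -0.23) and 9 erythroid and platelet genes (-0.06 with a mean of 0.04, 0.859; Alas2 0.31, Pf4 0.70).

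Of the 18 chromosome neighbours of P2ry14, 2 rose over all genes and adjusted over the list alone, Gpr171 and P2ry12. That list had a median of 0.01 and a mean of 0.32 (camera adjusted p = 0.016; adjusted p = 0.520 with an estimated correlation). It missed the threshold without WT library 2, 4 or 5 or P2ry14-null library 3 or 4 (camera adjusted p from 0.052 to 0.110), and its median, near 0, ran from -0.015 to 0.089 with single libraries left out. In all, 11 of 27 lists passed camera with the preset correlation, 3 higher and 8 lower. Another 10 lists passed in at least 1 fit with a library left out. These were glycolysis genes without WT library 2, 3 or 5 or P2ry14-null library 1 or 3, Gi signalling genes without WT library 2 or P2ry14-null library 1, and eosinophil identity genes without WT library 4 or P2ry14-null library 1. They were also monocyte genes without P2ry14-null library 1 or 3, T and NK cell genes without P2ry14-null library 1, epithelial genes without P2ry14-null library 5, and type 2, class II, alveolar macrophage and B cell genes without P2ry14-null library 2. With an estimated correlation 0 lists passed (smallest adjusted p = 0.215). The rotation test fry, which asks whether a list moves on balance in 1 direction, gave 0 lists (smallest adjusted p = 0.155). Its mixed form, for change in either direction, gave 1 list, the neighbours (adjusted p = 1.33e-09).

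**Figure D4:**
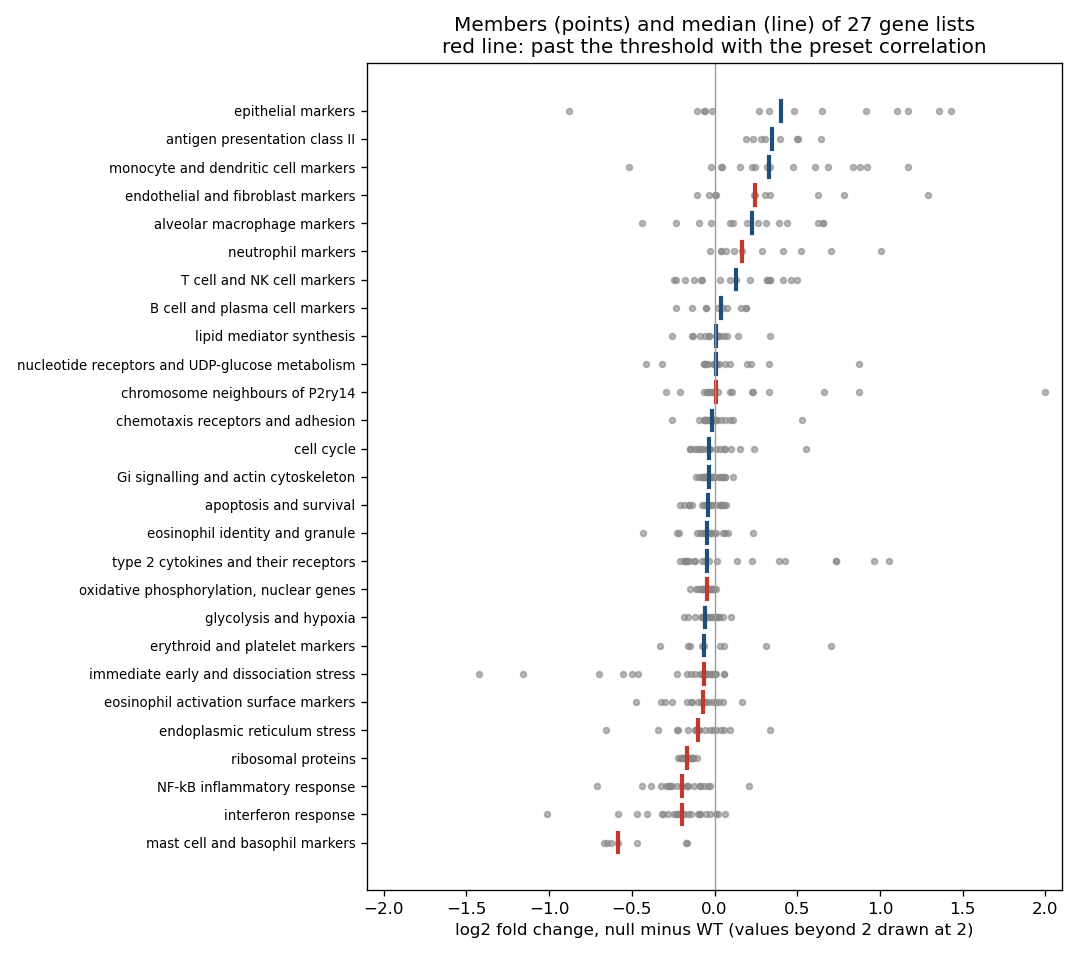
Log2 fold change of P2ry14-null over WT (horizontal axis; values beyond 2 drawn at 2) of the members of 27 gene lists (points) with each list's median (line). Red lines mark the 11 lists past the threshold with the preset correlation, from a median of -0.59 for mast cell and basophil genes to 0.24 for endothelial and fibroblast genes.

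The main axis of variation set 1 library apart and did not separate the groups. The leading principal component held 34.6% of the variance and set P2ry14-null library 2 at 29.8 against -8.39 to 0.19 for the other 9 (exact permutation adjusted p = 0.976 over 3 components). The next component held 21.4% and differed between the groups (exact permutation p = 0.0079, adjusted 0.024), with P2ry14-null library 1, the shallowest, at -21.9 and WT library 4 at 11.5. It missed the threshold without P2ry14-null library 1 or 2 or without any of the 5 WT libraries (adjusted p from 0.095 to 1), and over all tested genes (adjusted p = 0.286). Without P2ry14-null library 1 the component after it passed instead (adjusted p = 0.024). The remaining component held 11.0% (adjusted p = 0.976).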

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

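The tests of overlapping reads and of transcription running on for Gpr171 and P2ry12, of the flanking chromosome, of Mgst2 alone, of the counting interval of Gm30351 and of the NF-kB genes without P2ry14-null library 2 were chosen after the results were seen, and the relation of heat shock and NF-kB scores within groups was added after the covariate result. Within-group outliers were sought with Dixon's ratio in 186 sets of 5 libraries. It marked 29, where chance marks about 1 in 20 (9.3), and 17 of the 29 were in P2ry14-null library 2.

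P2ry14-null library 2 stood above the other 4 P2ry14-null libraries in genes that other lung cells express. It held 63.6 CPM of H2-Eb1 and 64.6 of H2-Ab1, both class II genes. It also held 13.5 CPM of Fabp5, 5.50 of Fabp4, 4.66 of surfactant protein gene Sftpb, 0.525 of Cldn18, 0.428 of Kdr and 0.798 of Pf4. Of lymphoid and neutrophil genes it held 3.48 CPM of Pax5, 0.993 of Mzb1 and 4.65 of S100a8. Il2rg was at 36.4 CPM against 34.0 to 34.3 in the others. Its list scores, the mean log2 difference from WT, were 1.71 for class II, 1.34 for monocyte and dendritic cell, 1.17 for alveolar macrophage, 0.640 for type 2 and 0.209 for nucleotide receptor genes.

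P2ry14-null library 1 was the shallowest, at 67.2 M reads against 129 to 151 in the others. Its mast cell and basophil score was -1.14 and its Cpa3 level 0.193 CPM. P2ry14-null library 3 held 33.7 CPM of the interferon-inducible Gbp2 against 11.6 to 13.6. P2ry14-null library 4 held 3286 CPM of Retnla, 1.44 of Eln and 4.68 of Stag3, the latter lowest. WT library 1 held 3464 CPM of Mcl1 and 519.6 of Ldha, both highest, and 10.7 of Tmem181a, lowest. WT library 3 had an erythroid and platelet score of -0.317, and WT library 5 held 4.71 CPM of Dynlt1b against 3.04 to 3.45.

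Gpr171 rose 12.8 kb downstream of P2ry14, and P2ry12 rose 62.8 kb upstream. Med12l, the sole gene that spans Gpr171, gained CPM equal to 4.46% of the gain of Gpr171, so Med12l as counted did not rise to match. With 0 shared exon bases and an unknown strand setting, reads between Med12l exons could count to Gpr171 alone, so this does not exclude them. Transcription from the P2ry14 promoter that runs on into Gpr171 is a candidate explanation. The log2 fold change of Gpr171 exceeds that of P2ry13, the nearest tested gene upstream on that strand, by 3.81. This restates the rise that prompted the explanation and does not decide. Neither does the gain of Gpr171, 22.3 CPM or 11.9% of the 188 CPM that P2ry14 lost. CPM is not scaled for length, and the annotation gives 2225 exon bases for Gpr171 and 11059 for P2ry14. The 11.9% is therefore a share of reads and not of transcripts. Transcription running on from P2ry14 is excluded for P2ry12, which lies upstream, at 62.8 kb. Overlapping reads stay open for P2ry12, since Med12l also spans it and shares 9 exon bases with it. Med12l rose from 5.61 to 6.60 CPM where P2ry12 rose from 1.59 to 2.93. A response of the eosinophils to the loss of the receptor was not tested apart from the edited chromosome and stays open for both genes, and read positions were not analysed here.

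Calls clustered around P2ry14, where a flanking chromosome segment of another strain may remain: between 0.5 and 10 Mb, calls were more frequent than elsewhere (Fisher's exact p = 5.29e-05), but Mgst2 and Gm30351, on which this rests, prompted the test, so this explanation and an effect of the genotype itself stay open. By counting error alone, the upper 95% limits of the read ratios are 16.8% of WT for Gm30351 and 32.9% for Mgst2, genes chosen after their values were seen. Both calls were kept in 10 of the 21 alternatives that tested both, with Gm30351 at log2 -3.90 to -3.31. A criterion set before this test took losses in most alternatives as a sign of few reads, so that explanation stays open for Gm30351. Mgst2 alone kept its call in 23 of 23 (-2.13 to -1.84) but not with the heat shock score as a covariate (-2.0 ± 0.33, edgeR adjusted p = 0.294). Other splits of the 10 libraries gave as many as 6 calls in 1 of 100, the real one, with 1 as the highest other. This count includes P2ry14, whose change the genotype fixes, and every other split mixes the genotypes, so it does not settle chance for single genes. Outside 10 Mb, 3 of 100 splits gave at least the 1 call of the real one, Il18rap, and 1 was again the highest other.

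NF-kB genes lay lower in P2ry14-null as a list. Without P2ry14-null library 2 the median was -0.189 (camera adjusted p = 8.33e-08), which argues against transcripts of other cells in that library, though with an estimated correlation the list did not pass (adjusted p = 0.421, all libraries). For the count of lists, chance cannot be excluded: 28 of 100 splits gave at least the 11 lists of the real one, and the highest other gave 18. With the heat shock score as a covariate the median was -0.0016, but the score, of 5 genes chosen after their values were seen, itself differs between the genotypes, so handling of the cells and genotype cannot be told apart by this test. Within groups the heat shock and NF-kB scores rose together (Pearson's r = 0.680), which is consistent with a handling or stress response that varies between libraries and may carry part of the difference, while an effect of the receptor on these genes stays open.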

How the results depend on the processing

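Alternatives leaving out a pair of libraries were chosen after seeing the data. The level of P2ry14 kept its call in all alternatives (log2 from -3.22 to -3.16), as did Gpr171 in 24 of 24 and Mgst2 in the 23 that tested it. Il18rap kept its call in 12 of 24 (adjusted p up to 1, with a fold of at least 1.2), P2ry12 in 10 of 23 (up to 0.281) and Gm30351 in 10 of 21 (up to 0.160). Against 6 calls, 2 higher and 4 lower, DESeq2 gave 18 (7 and 11), the filter of 5 CPM gave 3 (1 and 2) with fewer genes tested, and a fold of at least 1.2 gave 1 higher. Leaving out each library gave 3 to 5 calls, 1 to 2 higher and 2 to 4 lower; without P2ry14-null libraries 1 and 2, or P2ry14-null library 2 and WT library 4, 3 calls (1 and 2) remained, all shared. The cause was not tested beyond fewer samples. The 4 calls within 10 Mb lay between 1 and 4. Replicate numbers did not pair the libraries (correlations of same-numbered deviations from -0.093 to 0.094, and not every library correlated best with its own number); with the replicate block edgeR gave 6 calls, 1 higher, 3 of them shared and the others Il6, Hdc and Soat2, and DESeq2 41 (6 higher, 35 lower), 5 shared. Against 11 lists, the filter of 5 CPM gave 7, and an estimated correlation and fry gave 0. The component difference (adjusted p = 0.024) gave 0.095 with no filter, 0.393 with 5 CPM, 0.286 over all tested genes, 0.024 to 1 with each library left out, and 0.107 and 0.129 without those pairs, where so few libraries do not let a lone component pass over 3, so no loss is shown. With each library left out, medians ran from -0.353 to 0.517 for class II and from -0.246 to 0.380 for alveolar macrophage genes, reversed and past the threshold without P2ry14-null library 2. Without P2ry14-null libraries 1 and 2 they were -0.335 and -0.328, with monocyte (-0.171) and epithelial genes (-0.0734), and without P2ry14-null library 2 and WT library 4 they were -0.372, -0.291 and -0.240 for the former 3. Those of oxidative phosphorylation genes ran from -0.0833 to -0.0051, with camera's direction turned without WT library 1. Of 1501 comparisons of named genes other than P2ry14, 1444 kept their side of the threshold, mostly genes called in neither fit, and 21 gained a call. The 36 that lost it are those of Il18rap (12), P2ry12 (13) and Gm30351 (11) above. Of 588 comparisons of lists, 522 kept their side. Depth limits Gm30351, which rests on 6 reads over the P2ry14-null libraries.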

Other observations

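The test of close gene pairs below, with its 1.5-fold and 2 Mb limits, was chosen after the genes were seen. WT eosinophils carried a broad set of nucleotide receptors. P2rx1, an ATP-gated channel, was at 634 CPM in WT and 614 in P2ry14-null, P2ry10 at 300 and 306, P2ry2 at 129 and 128, and the ectonucleotidase Entpd1 at 385 and 369. P2ry14 at 211 CPM thus stood between P2ry10 and P2ry2 in WT by reads, which are not scaled for gene length. None of these 4 passed the threshold in edgeR. UDP-glucose handling genes also did not pass, with Ugp2 at 103 and 104 CPM, Ugdh at 53.6 and 54.0 and Uggt1 at 209 and 208. The adenosine receptor Adora2a was at 83.5 and 67.1 CPM and did not pass adjusted over the list alone (adjusted p = 0.148).

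WT library 4 stood apart in a small set of genes. It held 323 CPM of Hexim1, an inhibitor of transcription elongation, against 74.4 to 103.5 in the other WT libraries. It held 178 CPM of Nr4a3 against 46.6 to 96.0, 40.9 of Dusp2 against 11.6 to 16.8, and 30.2 of Gm34458 against 2.63 to 6.62.

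A pair of genes on chromosome 12 was high in P2ry14-null libraries 1 and 5 alone. Gm20658 was at 6.85 and 14.8 CPM in them and at 0.496 to 0.668 in the other 8 libraries, and Cdca7l at 3.75 and 3.66 against 0.812 to 1.16. Their starts, 116100553 and 117843473 of mm10, lie within 2 Mb. They were the 2 genes at least 1.5 times higher in both libraries than in every other, and random draws of 2 genes gave such a close pair with a one-sided permutation p of 0.0034. Of 45 pairs of libraries, 5 had at least 2 such genes, and 1 of these 5 had a close gene pair. A strain variant on chromosome 12 that segregates among the P2ry14-null mice is a hypothesis that may account for this, found and tested on the same data, so it stays open. On chromosome 17, Tmem181b-ps was at 39.6 and 40.5 CPM in the same libraries, 21.4 to 28.8 in the other P2ry14-null and 17.0 to 20.3 in the WT libraries. It was called higher in P2ry14-null by DESeq2, with and without the replicate block, and by edgeR without P2ry14-null library 4, and not by edgeR with all libraries. Dynlt1b and Tmem181a also lie on chromosome 17, with starts at 6430112 and 6256862. In P2ry14-null libraries 1 and 5, Dynlt1b was at 7.62 and 5.99 CPM, against 3.78 to 5.78 in the other P2ry14-null libraries. Tmem181a was at 15.8 and 16.2 against 13.8 to 14.1, so these higher values may not be independent.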
